A study of Mus musculus with 46 samples.

How the data were processed

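The data were 46 Affymetrix Mouse Genome 430 2.0 arrays, each carrying 45101 probe sets (groups of short probes that report on 1 transcript). Of these arrays, 24 held whole-ovary RNA from Foxo3 null mice and wild-type mice at 4 postnatal ages, with 3 arrays in each of 8 groups. Each ovary RNA came from the pair of ovaries of 1 pup and was amplified before labelling. The other 22 arrays stood alone: adult ovary, adult testis, testis of a Kitl mutant, 13 somatic tissues, wild-type and Foxo3 null embryos, microdissected oocytes, microdissected somatic ovarian cells, unfertilized eggs and cumulus granulosa cells. The design text also names embryonic stem cells and a further somatic tissue, for which the deposited values held no column, so they were not analysed here. Every deposited column mapped to a labelled sample, with 0 left over.

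The deposited values are linear array intensity signals, 1 per probe set and array. The submitters' processing notes name the Affymetrix software GCOS, version 1.4.0.036; its summary algorithm and settings are not given in the sources used here. The design text describes median scaling of each array on its own. The deposited intensities had a mean of 250 on every array once the lowest and highest 2% of probe sets were set aside, whereas the array medians ran from 55.3 to 147.8. They were therefore scaled to a common trimmed mean and not to a common median. Gene symbols came from the platform annotation. Of the probe sets, 34945 carried 1 symbol, 932 carried several, 9160 carried none and 64 were controls, and 18193 genes were named. No probe set was named for Cyp19a1 or Pten.

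Each array was rescaled so that its median equalled the common median of 93.5, which moved the ovary arrays by -0.64 to 0.45 log2 units. A pseudocount of 23.4 (0.25 of the common median) was added before taking log2. Probe sets with a mean signal over the ovary arrays of at least 46.8 (0.5 of the common median) were kept, which left 31649 probe sets and 14518 genes. A linear model with 1 mean per group was fitted to all 24 ovary arrays with limma 3.58.1 (eBayes with an intensity trend) in R 4.3.3, with input by the data.table package, version 1.17.8. The contrasts were null against wild-type at each age, their mean over the 4 ages, the difference of that effect between ages, and each step between successive ages in wild-type ovaries. All p-values are two-sided, and the Benjamini-Hochberg threshold was an adjusted p under 0.05. The precision of an array comparison is limited by the number of arrays, here 3 per group. A count of genes whose groups did not overlap is given beside the share of 10% that chance gives for 3 against 3.

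Before the data were examined, 24 lists of genes with known roles in oocytes, follicle cells, other cells of an ovary sample, signalling, metabolism and stress were fixed, together with the comparisons, tests and alternatives. Each gene was represented by its brightest probe set. Lists were compared with all other genes by camera in limma, with a preset correlation between genes of 0.01. Camera with a correlation estimated from the arrays and fry, which asks whether the genes of a list move on balance in 1 direction, were run as alternatives. For most lists that passed between genotypes, fold changes are also given relative to the median of all genes, which itself moved between groups. List changes between ages are given without this correction. List scores per array (the mean log2 of the list less the mean of all genes) were compared between genotypes by an exact permutation of the genotype labels within each age, with 160000 assignments. These comparisons of scores, and the camera tests of lists for the mean over ages and for differences between ages, were not in the plan and were added later. Where only 3 arrays were compared with 3, the smallest exact p was 0.1.

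A set of oocyte-enriched genes was defined from the single arrays alone: genes at least 4-fold higher both in microdissected oocytes than in microdissected somatic cells and in unfertilized eggs than in cumulus cells, with a signal of at least 2 times the common median. Single arrays were compared by fold only, with no test, since they had no replicates. For these comparisons a list's median ratio was placed among the medians of 10000 random lists of the same size and similar brightness, which is a rank among genes and not a p-value between samples. Ovary-selective genes were those at least 4-fold higher in ovary than in the highest of the 13 somatic tissues.

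Genes were named by a fixed rule: the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, up to 4 members past the threshold for each list, and 17 genes chosen for their roles in the ovary, whatever their test gave (no probe set is listed for Cyp19a1 and Pten among them). In single-array comparisons the 10 largest ratios each way were taken among genes whose brighter array reached 4 times the common median, and for ovary-selective genes the 15 largest. Members of a list that did not pass the threshold are named as examples of the list, and that choice was made after their values were seen.

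RNA quality was read from the 3-prime to 5-prime signal ratios of the Gapdh and beta-actin control probe sets, which rise when transcripts are shortened at the 5-prime end. The alternatives were the signals as deposited, quantile normalization, no pseudocount or a larger one, other filters, a model without the trend, other choices of probe set, only the 6 arrays compared, a replicate block, and leaving out each array in turn. A Gapdh ratio above 8 was the limit for further fits chosen after the control ratios were seen: without the 7 arrays above it, with the ratio as a covariate, and with array weights.

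The procedure was tested on simulated data, with 50 genes changed at each fold among 31649 and spread taken from the residuals of the real arrays. At PD14 the model recovered 0%, 34%, 58% and 92% of genes changed 2-fold, 3-fold, 4-fold and 8-fold, with 0 false calls in the single shuffle drawn. The mean over ages recovered 72% of 2-fold changes, and the difference between ages 24% of 4-fold changes. In the simulation of the PD14 against PD7 step, the shuffled residuals of the real arrays gave 5876 false calls, against 9 with independent spread. Changes shared by many genes on a few arrays look like group differences. Each contrast was simulated with a single shuffle, so 0 false calls at PD14 and 5876 here do not rank the contrasts. On the real arrays, a wrong split of the PD3 genotypes gave 5049 calls. Among 24 lists with no change added, camera with the preset correlation called 2.75 on average over 20 shuffles and 9 at most, and camera with the estimated correlation called 0. The list raised by 1 log2 unit was simulated with independent spread only, and was called with either correlation. Whether camera with the estimated correlation would call such a list among the correlated residuals of the real arrays was not simulated.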

Results

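RNA from whole ovaries was measured on 24 Affymetrix 430 2.0 arrays. They covered wild-type and Foxo3 null mice at postnatal days (PD) 1, 3, 7 and 14, with 3 arrays for each age and genotype. FOXO3 is a forkhead transcription factor of the PI3K pathway, and mice without it are known for the early and widespread activation of their primordial follicles. A further 22 arrays, without replicates, covered adult ovary and testis, the testis of a Kitl mutant that is nearly devoid of germ cells, 13 somatic tissues, embryos of both genotypes, microdissected oocytes and somatic ovarian cells, and unfertilized eggs with their cumulus cells. Adult tissues were taken at 6 weeks except the placenta (9 weeks) and the Kitl mutant testis (16 weeks), embryos at E11.5, and eggs and microdissected cells at 3 weeks. The sample titles name the FVB strain for the wild-type adult tissues, eggs, cumulus cells and microdissected cells. They name no strain for the Kitl mutant testis or for the Foxo3 ovaries and embryos. Eggs and cumulus cells came from mice given 5 IU of each of a pair of gonadotropins 42 hours apart and were collected 24 hours after the later injection. Arrays have no sequencing depth, and the median deposited signal ran from 68.4 to 146 on the ovary arrays and from 55.3 to 147.8 over all 46 arrays. Signals below are median-scaled signals given as mean ± SD with n = 3 unless stated, and changes are log2 differences with their standard error (SE). Each ovary RNA came from 1 animal, but the labels do not say that replicates were different litters or batches, so all p-values measure only the spread between arrays as labelled.

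The 3-prime to 5-prime ratio of the Gapdh control transcript, a sign of shortened RNA, varied widely among the amplified ovary samples. It lay between 8.64 and 29.2 on 7 arrays and between 2.44 and 7.88 on the other 17, against 0.730 to 1.57 on the 18 arrays made directly from 5 µg of RNA. The 7 arrays were PD1 Foxo3 null replicates 2 and 3, PD3 wild-type replicates 2 and 3, PD3 Foxo3 null replicate 3, PD7 wild-type replicate 3 and PD14 wild-type replicate 3. The ratio did not separate the genotypes across the 4 ages (exact stratified permutation p = 0.982 for Gapdh and 0.626 for beta-actin, n = 12 per genotype), but differences at single ages went both ways. The log2 ratio in null less wild-type ovaries was 0.96 at PD1 and -0.55 at PD3 for Gapdh and 1.51 and -0.98 for beta-actin (exact permutation p = 0.5, 0.5, 0.3 and 0.3, n = 3). The leading principal component of the ovary arrays held 40.7% of the variance and followed the log2 Gapdh ratio (r = 0.69, permutation p = 1e-04; rho = 0.65, permutation p = 6e-04; r = 0.78 without the 2 most distant arrays, n = 24). Within groups, several of the 25 gene lists scored per array followed the ratio as well. TGF-beta and BMP signalling genes had r = -0.90 (rho = -0.89, r = -0.85 without the 2 most distant arrays, permutation p = 8e-05, adjusted p = 0.002 over the 25 lists). Smooth muscle genes had r = -0.86 (rho = -0.87, r = -0.85 without these 2, adjusted permutation p = 0.0025), PI3K, AKT and mTOR genes r = -0.79 (rho = -0.84, -0.78 without them, adjusted permutation p = 0.00258) and endothelial genes r = -0.58 (rho = -0.55, -0.57, adjusted permutation p = 0.0425). Kidney and mesonephric genes went the other way with r = 0.73 (rho = 0.76, 0.81 without these 2 arrays, adjusted permutation p = 0.039), and so did oviduct and ciliated cell genes with r = 0.69 (rho = 0.71, 0.73, adjusted permutation p = 0.0288). For the zona, maternal-effect, germ cell regulator and cell division lists r lay between -0.09 and 0.26 and did not pass, although without the 2 most distant arrays it lay between -0.26 and -0.55. The oocyte-enriched set had r = -0.08 (adjusted permutation p = 0.879), and -0.59 without these 2 arrays.

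The targeted gene was examined on every array. Foxo3 (Entrez 56484) lies on chromosome 10 at 42181845-42276695 (GRCm38.p6), and the long noncoding gene Gm38485 lies within that span at 42247436-42274809. The probe set listed for both genes, called the shared probe set below, was lower in null ovaries at every age. Its signal was 831 ± 418 in wild-type and 112 ± 36.7 in null ovaries at PD1, 355 ± 202 and 218 ± 246 at PD3, 187 ± 56.1 and 39.5 ± 22.1 at PD7, and 143 ± 42.8 and 44.3 ± 11 at PD14. The log2 changes were -2.55, -0.99, -1.76 and -1.28, and the mean over the 4 ages was -1.65 (exact stratified permutation p = 0.000162, adjusted p = 0.000648 over 4 probe sets). Within 1 age the exact permutation p was 0.1, 0.3, 0.1 and 0.1, where 0.1 is the smallest that 3 against 3 can give. The array labelled PD3 Foxo3 null replicate 3 went against its label, with a signal of 501 against 61.6 and 90.2 on the other PD3 null arrays and 169 to 569 on the PD3 wild-type arrays. The 3 probe sets listed for Foxo3 alone were not lower in null ovaries, with mean changes of 0.14 for the brightest (exact permutation p = 0.512), 0.16 for the middle (exact permutation p = 0.364) and 0.71 for the faintest (exact permutation p = 0.0804). The labels do not say which part of the gene was removed, and a probe set outside that part checks nothing. On the single embryo arrays the shared probe set read 71.0 in the null and 82.9 in the wild-type embryo.

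**Figure D1:**
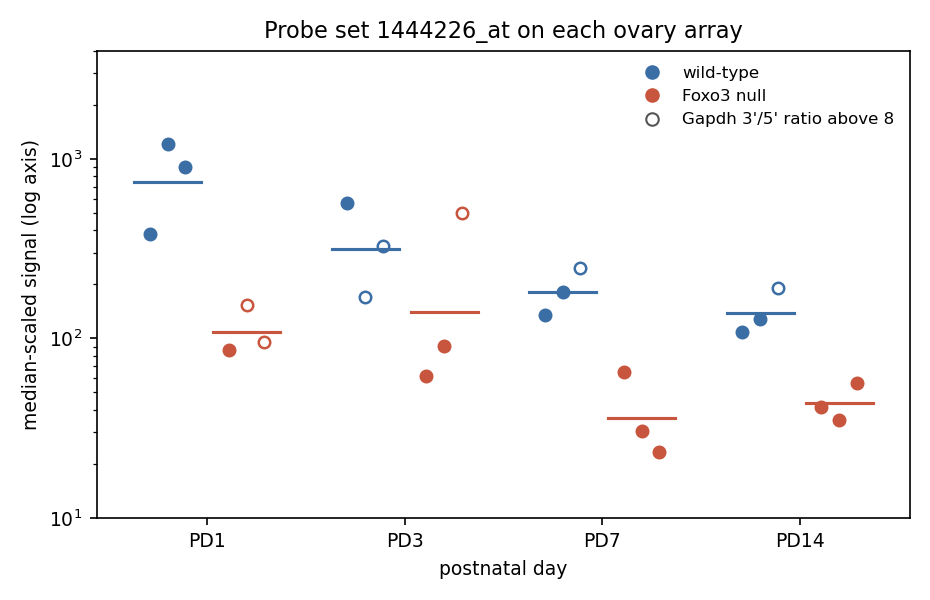
Median-scaled signal of the probe set shared by Foxo3 and Gm38485 (log axis) on each of the 24 ovary arrays by postnatal day and genotype; bars are geometric means and open symbols mark the 7 arrays with a Gapdh ratio above 8. The array labelled PD3 Foxo3 null replicate 3, at 501, lies within the PD3 wild-type range of 169 to 569.

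The comparison of null with wild-type ovaries at each age asked which genes respond to the loss of Foxo3 as follicles form and begin to grow. At PD1 oocyte genes had lower values in null ovaries, and no list passed. Ddx4, the germ cell RNA helicase, changed by -0.95 (SE 0.421) and Fshr, the follicle-stimulating hormone receptor of granulosa cells, by 0.67 (SE 0.286). Gdf9, a growth factor secreted by oocytes, changed by -0.65 (SE 0.57) and Zp3, a zona pellucida protein, by -0.73 (SE 0.714). By limma 0 of 31649 probe sets passed at PD1, 1367 had an unadjusted p under 0.05 (440 higher, 927 lower) against 1582 by chance, and the smallest adjusted p was 0.507. Among 14518 genes 1266 (8.72%) had groups that did not overlap, where chance gives 10%. None of the 24 lists passed by camera. The nearest were 4 lists at an adjusted p = 0.06: the oviduct list (mean 0.25, 7 of 9 genes higher), germ cell regulators (-0.43, 17 of 18 lower), the maternal-effect list (-0.64, 16 of 20 lower) and ribosomal proteins (0.16, 10 of 15 higher). The median of all probe sets moved by -0.16, and 2 of the 3 null arrays at this age had Gapdh ratios above 8. Leaving out PD1 wild-type replicate 1 gave 1 probe set past the threshold.

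At PD3 the oocyte lists were higher in null ovaries. Zona and oocyte-secreted genes rose relative to other genes (mean 0.78 with 8 of 8 higher, or 0.54 relative to the all-gene median, camera adjusted p = 0.019), with Zp3 at 1.36 (SE 0.714) and Zp1 at 1.28 (SE 0.542). Maternal-effect genes, whose products are stored in the egg, rose as a list (0.75, 19 of 20 higher, 0.51 relative, adjusted p = 0.00927), and so did the germ cell regulators (0.47, 17 of 18 higher, 0.22 relative, adjusted p = 0.0278). Ddx4 stood at 0.91 (SE 0.421) and Kitl, the granulosa-derived ligand of the oocyte receptor Kit, at 1.14 (SE 0.477). Cell division genes (0.55, 23 of 24 higher, 0.30 relative, adjusted p = 0.00407), cholesterol synthesis genes (0.48, 16 of 16, 0.23 relative, adjusted p = 0.0396) and mitochondrial respiration genes (0.52, 22 of 22, 0.28 relative, adjusted p = 0.0396) rose relative to other genes as well. Kidney and mesonephric genes fell as a list (mean -0.26 with 5 of 7 lower, adjusted p = 0.0104). With an estimated correlation every one of these calls was lost: adjusted p = 0.96 with an estimated correlation for all but the kidney list, and adjusted p = 0.174 with an estimated correlation for that list. No member passed over all genes or when adjusted over the list alone. By limma 0 probe sets passed, 865 had an unadjusted p under 0.05 (656 higher, 209 lower) against 1582 by chance, and 777 genes (5.35%, chance 10%) had groups that did not overlap.

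The PD3 lists depended on single arrays. Without PD3 Foxo3 null replicate 1 the camera adjusted p was 0.999 for the zona list, 0.928 in the opposite direction for the maternal-effect list, 0.247 for cell division, 0.749 for cholesterol synthesis and mitochondrial respiration and 0.0879 for the kidney list. Without PD3 wild-type replicate 3 it was 0.117 for the germ cell regulators, and without PD3 wild-type replicate 1 limma called 2 probe sets. The null group includes replicate 3, whose shared probe set went against its label. Without that array limma called 0 probe sets, and the camera adjusted p was 1.26e-05 for the maternal-effect list and 0.00545 for the kidney list. The fit without the 7 arrays of high Gapdh ratio leaves 1 wild-type and 2 null arrays at PD3, with the spread taken from the other groups. In it the zona (4.38e-06) and maternal-effect (1.08e-06) lists passed by camera and mitochondrial respiration turned direction (adjusted p = 0.853), but these values rest on a single wild-type array.

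At PD7 null ovaries carried more signal from genes of growing oocytes. The Gdf9 signal was 6365 ± 1924 in null and 2836 ± 897 in wild-type ovaries (1.17, SE 0.57), and that of Zp3 was 8567 ± 2895 and 3191 ± 1213 (1.45, SE 0.714). For both genes all 3 null arrays lay above all 3 wild-type arrays, and neither passed the threshold. Zona and oocyte-secreted genes rose as a list (mean 0.88, 8 of 8 higher, 0.77 relative to the all-gene median, camera adjusted p = 0.00027; adjusted p = 0.659 with an estimated correlation). Maternal-effect genes rose as well (0.91, 20 of 20 higher, 0.80 relative, adjusted p = 5.34e-08; adjusted p = 0.659 with an estimated correlation), with Padi6 at 1.99 (SE 0.671) and Khdc3 at 1.64 (SE 0.536), both parts of the subcortical maternal complex of the egg. Germ cell regulators rose as well (0.35, 14 of 18 higher, 0.24 relative, adjusted p = 0.0427), as did cell division genes (0.43, 21 of 24, 0.32 relative, adjusted p = 0.00287), ribosomal proteins (0.47, 14 of 15, 0.36 relative, adjusted p = 0.034) and mitochondrial respiration (0.50, 21 of 22, 0.39 relative, adjusted p = 0.00287), and each of these 4 had an adjusted p = 0.977 with an estimated correlation.

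In the opposite direction at PD7, kidney and mesonephric genes fell as a list (mean -0.45 with 5 of 7 lower, -0.56 relative, camera adjusted p = 7.67e-05). Among the 22 list calls at single ages this was the only one that held with an estimated correlation (adjusted p = 0.0205), although fry, which tests a list on its own, gave an adjusted p = 0.187. Its largest member was Umod, the uromodulin gene of the kidney tubule, at -1.43 (SE 0.34), the only gene to pass when adjusted over the list alone, against 0 over all genes. The score of this list followed the Gapdh ratio within groups (r = 0.73), and 1 of the 3 wild-type arrays at PD7 but no null array had a ratio above 8. FOXO target genes, chosen as known direct targets of the factor, lay lower than other genes (mean -0.08 with 15 of 22 lower, -0.19 relative, adjusted p = 0.0427; adjusted p = 0.977 with an estimated correlation). By limma 0 probe sets passed at PD7, 690 had an unadjusted p under 0.05 (452 higher, 238 lower) against 1582 by chance, and 2315 genes (15.9%, chance 10%) had groups that did not overlap. Leaving out PD7 Foxo3 null replicate 2 gave 1 probe set past the threshold and an adjusted p of 0.171 for the germ cell regulators. Leaving out PD7 Foxo3 null replicate 3 gave 0.961 for ribosomal proteins and 0.0836 for mitochondrial respiration, and leaving out PD7 wild-type replicate 2 gave 0.277 for FOXO targets (camera adjusted p-values).

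At PD14 the same oocyte lists were higher in null ovaries and germ cell regulators were among them. The Ddx4 signal was 1282 ± 141 in null and 553 ± 198 in wild-type ovaries (1.24, SE 0.421), that of Bmp15, an oocyte growth factor, was 927 ± 115 and 533 ± 146 (0.80, SE 0.35), that of Gdf9 was 8593 ± 1495 and 4381 ± 1103 (0.99, SE 0.57), and that of Zp3 was 10670 ± 2751 and 5213 ± 2294 (1.11, SE 0.714). Kit changed by 0.74 (SE 0.314). In all 5 genes the 3 null arrays lay above the 3 wild-type arrays, and none passed the threshold. Germ cell regulators rose as a list (mean 0.64, 17 of 18 higher, 0.42 relative to the all-gene median, camera adjusted p = 3.16e-05; adjusted p = 0.367 with an estimated correlation), with 3 members past the threshold when adjusted over the list alone and 0 over all genes. Zona genes rose (0.92, 8 of 8, 0.70 relative, adjusted p = 0.000698; adjusted p = 0.43 with an estimated correlation; 3 past the threshold adjusted over the list alone), with Zp1 at 1.78 (SE 0.542). Maternal-effect genes rose (0.72, 19 of 20, 0.49 relative, adjusted p = 0.0101; adjusted p = 0.868 with an estimated correlation). Cell division genes rose as a list (0.73, 24 of 24 higher, 0.51 relative, adjusted p = 2.07e-07; adjusted p = 0.43 with an estimated correlation). In both lists 0 members passed adjusted over the list alone, with the mitotic kinase Plk1 at 1.13 (SE 0.509) and the checkpoint kinase Bub1 at 1.12 (SE 0.492).

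Other lists were lower at PD14. Macrophage and leukocyte genes fell relative to other genes (mean -0.10 with 7 of 12 lower, -0.32 relative, camera adjusted p = 0.0323; adjusted p = 0.367 with an estimated correlation), as did kidney and mesonephric genes (-0.22 with 6 of 7 lower, -0.45 relative, adjusted p = 0.0161; adjusted p = 0.28 with an estimated correlation) and ribosomal proteins (-0.10 with 12 of 15 lower, -0.32 relative, adjusted p = 0.0368; adjusted p = 0.885 with an estimated correlation). Inhba, a subunit of activin and inhibin in granulosa cells, read 348 ± 206 in null and 1270 ± 952 in wild-type ovaries (-1.50, SE 0.737), and Kitl changed by -0.67 (SE 0.477), neither past the threshold. Of the remaining fixed genes, Cyp17a1, an enzyme of androgen synthesis, changed by -0.72 (SE 0.883), Star by -0.26 (SE 0.269), Cdkn1b by 0.69 (SE 0.497), Nobox by 0.86 (SE 0.397) and Figla by 0.11 (SE 0.446), and Amh was below the filter on low signals (144 ± 95.8 and 99.6 ± 86.6). By limma 0 probe sets passed at PD14, 1300 had an unadjusted p under 0.05 (1033 higher, 267 lower) against 1582 by chance, the smallest adjusted p was 0.176, and 2045 genes (14.1%, chance 10%) had groups that did not overlap. In the fit without the 7 arrays limma called 2 probe sets at PD14, and the kidney (adjusted p = 0.53) and macrophage (0.164) lists no longer passed by camera. Leaving out PD14 wild-type replicate 3 gave 0.394 and 0.35 for these lists, and leaving out PD14 Foxo3 null replicate 3 gave 0.446 for ribosomal proteins. The lists of meiotic prophase, granulosa cells, theca, stroma, smooth muscle, surface epithelium, oviduct, endothelium, erythroid cells, adipose tissue, PI3K, AKT and mTOR signalling, TGF-beta and BMP signalling, cell death and early stress passed at no age by camera, the smallest adjusted p being 0.06.

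**Figure D2:**
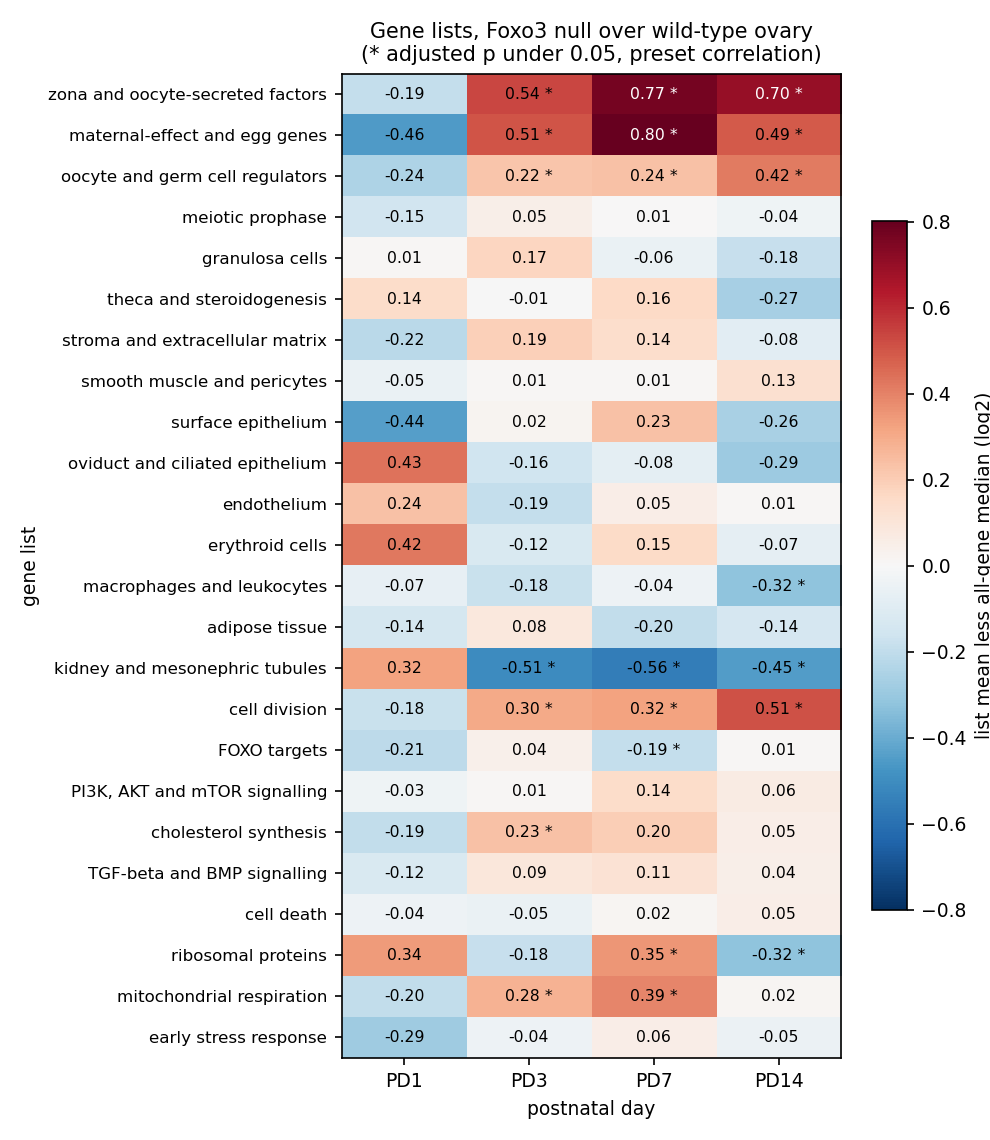
Mean log2 change of each of the 24 gene lists in Foxo3 null against wild-type ovaries (3 arrays each) less the median of all genes, by postnatal day; asterisks mark camera adjusted p under 0.05 with the preset correlation. The zona list lies at 0.54, 0.77 and 0.70 on days 3, 7 and 14, and of the 22 marked cells 1, the kidney list on day 7, keeps its mark with an estimated correlation.

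Averaged over the 4 ages, zona genes (camera adjusted p = 9.64e-06), maternal-effect genes (1.96e-05), germ cell regulators (0.00201) and cell division genes (2.29e-06) were higher in null ovaries, with adjusted p = 0.422 for zona genes and 0.631 for the other 3 lists with an estimated correlation. Kidney genes were lower (mean -0.20, camera adjusted p = 8.22e-05; adjusted p = 0.0269 with an estimated correlation), but their score followed the Gapdh ratio within groups (r = 0.73), and high ratios were more frequent in wild-type than in null arrays at PD3, PD7 and PD14. Permuting genotype labels within ages gave weaker evidence. The zona score differed by 0.45 (higher in null at 3 of 4 ages, exact permutation p = 0.0296), the cell division score by 0.24 (3 of 4 ages, exact permutation p = 0.0464), the macrophage score by -0.15 (lower at 4 of 4 ages, exact permutation p = 0.0396), the maternal-effect score by 0.34 (3 of 4 ages, exact permutation p = 0.118), the germ cell regulator score by 0.16 (3 of 4 ages, exact permutation p = 0.068) and the kidney score by -0.30 (lower at 3 of 4 ages, exact permutation p = 0.0909). None passed over the 24 lists, the smallest adjusted p being 0.371. For single genes limma called 0 probe sets for the mean over ages (1081 with an unadjusted p under 0.05, smallest adjusted p 0.0912) and 0 for the difference between ages (965, smallest adjusted p 0.989). The fit without the 7 arrays, which leaves 1 null array at PD1 and 1 wild-type array at PD3, called 2 for the mean, both lower in null: the shared probe set (-2.02, adjusted p = 0.00381) and Ctxn3 (-1.28, adjusted p = 0.00559), the latter named after its value was seen. Leaving out PD3 Foxo3 null replicate 3 gave 3 probe sets for the mean, leaving out PD7 Foxo3 null replicate 2, PD1 wild-type replicate 1 or PD3 wild-type replicate 2 gave 1, and leaving out PD3 wild-type replicate 1 gave 1 for the difference between ages. Median scaling left a median change over all probe sets of -0.16, 0.17, 0.06 and 0.16 at PD1, PD3, PD7 and PD14 against 0.05, -0.10, -0.09 and -0.10 with signals as deposited. List changes are therefore also given relative to the all-gene median, taken over 1 probe set per gene, which was -0.182, 0.245, 0.111 and 0.224. Changes of single genes are given without this correction. Rescaling moved most arrays with a Gapdh ratio above 8 down, from -0.39 for PD7 wild-type replicate 3 to -0.64 for PD3 wild-type replicate 3. PD1 Foxo3 null replicate 3 moved by only -0.03. Among the other ovary arrays the lowest shift was -0.09, for PD7 Foxo3 null replicate 3.

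**Figure D3:**
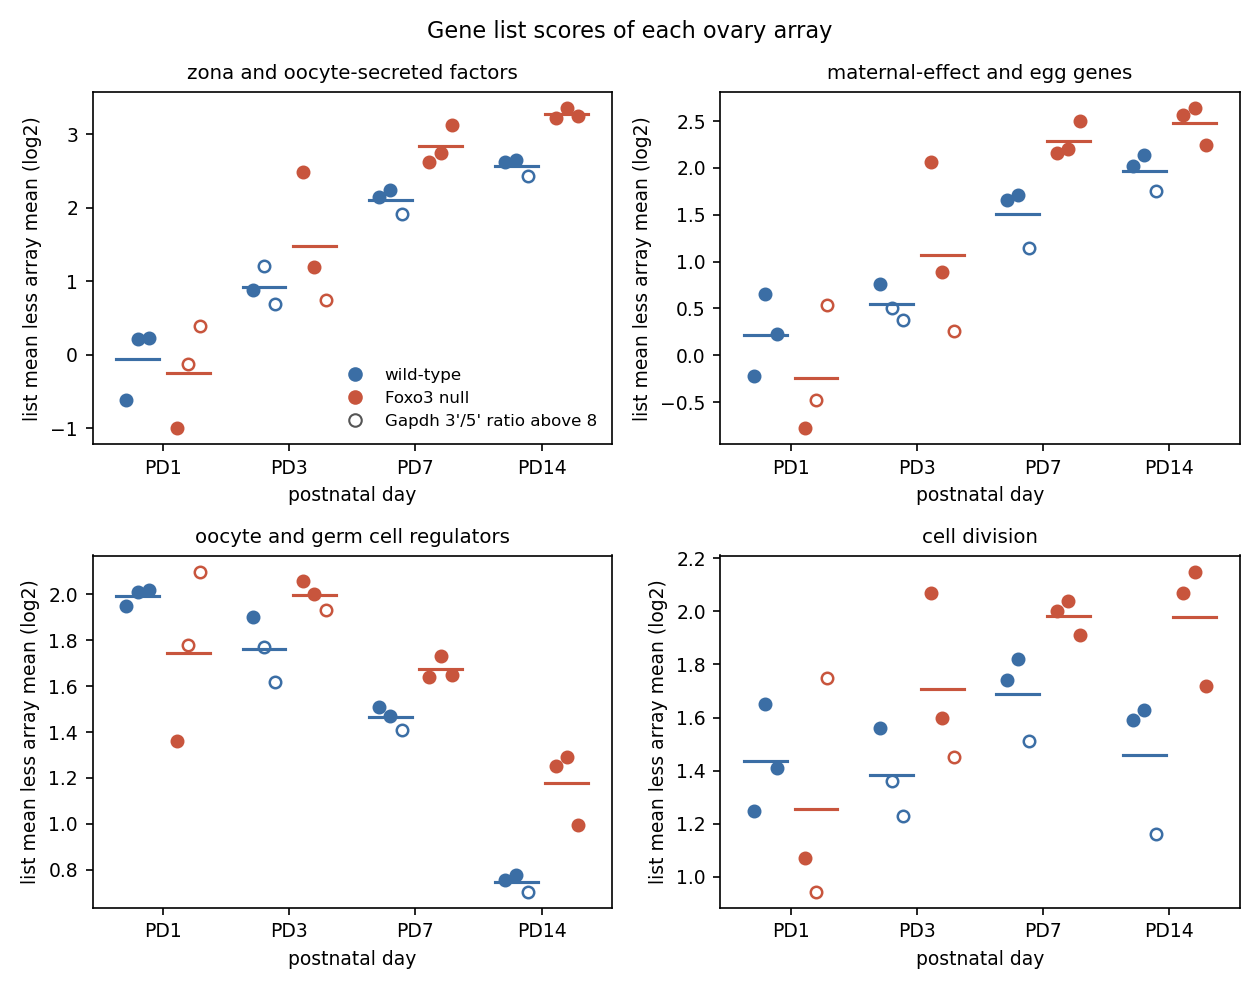
Score of 4 gene lists (mean log2 signal of the list less the mean of all genes) on each of the 24 ovary arrays by postnatal day and genotype. Short horizontal lines mark the means of 3 arrays, and open symbols the arrays with a Gapdh ratio above 8. For the zona list all 3 null arrays lie above all 3 wild-type arrays on days 7 and 14, and the mean difference over the 4 ages is 0.45.

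A set of 399 genes enriched in oocytes was defined on the microdissected and egg arrays, apart from the ovary arrays, and 397 were measured in the ovary. It was lower in null ovaries at PD1 (mean -0.39, 70 higher, camera adjusted p = 1.32e-05) and higher at PD3 (0.53, 379 higher, 5.29e-12), PD7 (0.49, 351 higher, 3.19e-15) and PD14 (0.66, 378 higher, 4.98e-22). With an estimated correlation none of these calls held: adjusted p = 0.463, 0.336, 0.336 and 0.336 with an estimated correlation at the 4 ages. Adjusted over the list alone, 0, 1, 1 and 15 genes passed, against 0 over all genes at each age. The means and counts above include the shift of all genes. As a score, less the mean of all genes, the set stood at 0.012 in null and 0.219 in wild-type ovaries at PD1. The scores were 0.612 and 0.307 at PD3, 1.114 and 0.763 at PD7, and 1.371 and 0.921 at PD14. Permuting genotype labels within ages gave a mean score difference of 0.22 (higher at 3 of 4 ages, exact permutation p = 0.0384). The PD1 call was lost without PD1 Foxo3 null replicate 1 (adjusted p = 0.301). A somatic-enriched set, planned by the same rule in the other direction, held 0 genes. That rule also asks for a 4-fold lower signal in eggs than in cumulus cells, which only 11 genes reached in the comparison of these arrays. Cumulus cell transcripts were abundant on the egg array, so the empty set says little about somatic genes of the ovary. The oocyte-enriched set therefore has no somatic counterpart.

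The steps between successive ages in wild-type ovaries asked how the ovary changes from the breakdown of germ cell nests to the first growing follicles. From PD1 to PD3 genes of meiosis fell. Taf7l, a germ cell partner of the basal transcription machinery, dropped from 1244 ± 238 to 190 ± 108 (-2.66, SE 0.382, limma adjusted p = 0.0103), and the other probe set past the threshold carried no gene symbol. Both calls went down, 3602 probe sets had an unadjusted p under 0.05 (873 higher, 2729 lower) against 1582 by chance, and 2515 genes (17.3%, chance 10%) had groups that did not overlap. Meiotic prophase genes fell as a list (mean -0.74 with 18 of 20 lower, camera adjusted p = 0.00126; adjusted p = 0.627 with an estimated correlation), and 7 passed when adjusted over the list alone, against 0 over all genes. The synaptonemal complex genes Syce3 (-2.5, SE 0.48), Tex12 (-2.04, SE 0.597) and Sycp1 (-1.55, SE 0.41) were among the lowest. Zona genes rose (0.69, 7 of 8 higher, adjusted p = 0.000964; adjusted p = 0.627 with an estimated correlation). Mitochondrial respiration fell (-0.86, 22 of 22 lower, adjusted p = 0.00137; adjusted p = 0.817 with an estimated correlation), and so did the early stress response (-0.87, 16 of 17 lower, adjusted p = 0.00143; adjusted p = 0.709 with an estimated correlation). The median of all probe sets moved by -0.19, a shift that the list means above include. Of the 3 PD3 arrays 2, but no PD1 array, had Gapdh ratios above 8. Leaving out any of the 3 PD1 arrays or PD3 replicate 3 gave 0 probe sets, PD3 replicate 2 gave 1 and PD3 replicate 1 gave 10. The camera adjusted p was 0.456 for early stress without PD1 replicate 1 and 0.0693 for mitochondrial respiration without PD1 replicate 2.

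From PD3 to PD7 genes of growing follicles rose. Khdc1b, an oocyte KH domain gene, went from 296 to 2588 (3.06, SE 0.533, limma adjusted p = 0.0266), Oosp1, an oocyte-secreted protein, from 250 to 2041 (2.94, SE 0.563, adjusted p = 0.0449), and Pramel29 rose by 3.12 (SE 0.438, adjusted p = 0.00613). Nr5a2, a nuclear receptor of granulosa cells, rose from 306 to 1353 (2.05, SE 0.383, adjusted p = 0.0416). Rises were also called for Steap4 (2.62), Nfe2l2 (2.56), Enpep (2.5) and Col4a4 (2.39), while Tktl1, a transketolase-like gene, fell from 798 to 139 (-2.30, SE 0.3, adjusted p = 0.00395). In all 38 probe sets passed, 36 up and 2 down, standing for 28 genes. The count depended on the scaling and was higher with signals as deposited and with quantile normalization. Zona genes rose as a list (8 of 8 higher, mean 1.38, camera adjusted p = 2.37e-06; adjusted p = 0.74 with an estimated correlation; 3 passed adjusted over the list alone and 1 over all genes). Maternal-effect genes rose as well (19 of 20 higher, 1.16, adjusted p = 7.62e-07; adjusted p = 0.749 with an estimated correlation; 7 passed adjusted over the list alone and 0 over all genes). Granulosa cell genes rose as a list (18 of 21 higher, 1.04, adjusted p = 7.98e-07; adjusted p = 0.74 with an estimated correlation; 10 passed adjusted over the list alone and 1 over all genes), with Inhbb at 2.41 (SE 0.61) and Kitl at 1.94 (SE 0.477). Stroma (0.82, 12 of 13 higher, adjusted p = 0.0229), cell division (0.51, 20 of 24, adjusted p = 0.0229) and cholesterol synthesis (0.60, 15 of 16, adjusted p = 0.0059) rose as lists, with an adjusted p = 0.749, 0.832 and 0.749 with an estimated correlation. Germ cell regulators fell relative to other genes (-0.10, 10 of 18 lower, adjusted p = 0.0155; adjusted p = 0.749 with an estimated correlation), with Mov10l1 at -1.07 (SE 0.286) and Mael at 1.44 (SE 0.563).

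For this step 2737 probe sets had an unadjusted p under 0.05 and 1904 genes (13.1%, chance 10%) had groups that did not overlap. Leaving out 1 array moved the count of 38 to 1, 0 and 8 without PD7 replicates 1, 2 and 3, and to 146, 3 and 2 without PD3 replicates 1, 2 and 3, and the fit without the 7 arrays of high Gapdh ratio, with 1 array left at PD3 and 2 at PD7, gave 0. The camera adjusted p was 0.212 for germ cell regulators and 0.0557 for cholesterol synthesis without PD3 replicate 1, 0.074 for stroma without PD3 replicate 3 and 0.0934 for cell division without PD7 replicate 2.

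From PD7 to PD14 theca and steroidogenesis genes rose and meiotic genes fell further. Car14, a membrane carbonic anhydrase, went from 15.3 to 593 (3.68, SE 0.517, limma adjusted p = 0.00325), Smoc2, a matricellular protein, from 234 to 1792 (2.78, SE 0.288, adjusted p = 7.84e-05), and Obox2, an oocyte homeobox gene, from 195 to 1749 (3.00, adjusted p = 0.00435). Nr5a2 rose again, from 1353 to 5428 (1.90, adjusted p = 0.037), and Foxo1, a forkhead factor of granulosa cells, rose from 566 to 2073 (1.78, adjusted p = 0.0322). Tktl1 fell again, from 139 to 5.91 (-2.46, adjusted p = 0.000646). For Car14 and Tktl1 the lower mean lies below the pseudocount of 23.4, so the size of these changes depends on it. Cyp17a1 went from 47.7 ± 34.7 to 1776 ± 1962 (3.96, SE 0.883), short of the threshold (adjusted p = 0.0703). In all 62 probe sets passed, 58 up and 4 down, standing for 46 genes. The share of falls depended on the scaling, with 71 up and 37 down for signals as deposited and 67 up and 30 down with quantile normalization. Theca and steroidogenesis genes rose as a list (8 of 9 higher, mean 1.18, camera adjusted p = 0.000188; adjusted p = 0.154 with an estimated correlation; 5 passed adjusted over the list alone and 0 over all genes). Smooth muscle genes rose as a list (8 of 10 higher, 0.82, adjusted p = 0.00347; adjusted p = 0.318 with an estimated correlation; 4 passed adjusted over the list alone), with Myh11 at 1.90 (SE 0.429). Meiotic prophase genes fell as a list (17 of 20 lower, -0.59, adjusted p = 1.57e-09), a call that held with an estimated correlation (adjusted p = 0.0371) and with fry (adjusted p = 0.0337); 6 passed adjusted over the list alone and 0 over all genes, and Sycp3, of the synaptonemal complex, stood at -1.73 (SE 0.368). Germ cell regulators fell as a list (16 of 18 lower, -0.59, adjusted p = 1.57e-09; adjusted p = 0.143 with an estimated correlation; 2 passed adjusted over the list alone), with Mael at -1.48 (SE 0.563) and Figla at -1.16 (SE 0.446).

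Further lists passed between PD7 and PD14. Maternal-effect genes rose (mean 0.59, 17 of 20 higher, camera adjusted p = 0.0138; adjusted p = 0.708 with an estimated correlation), and so did PI3K, AKT and mTOR genes (0.50, 13 of 17, adjusted p = 0.019; adjusted p = 0.701 with an estimated correlation), TGF-beta and BMP genes (0.39, 24 of 27, adjusted p = 0.0404; adjusted p = 0.708 with an estimated correlation) and ribosomal proteins (0.60, 15 of 15, adjusted p = 0.0335; adjusted p = 0.708 with an estimated correlation). Macrophage genes fell (-0.23, 9 of 12 lower, adjusted p = 0.0192; adjusted p = 0.161 with an estimated correlation), and cell division genes lay lower than other genes (-0.10, 15 of 24 lower, adjusted p = 0.0404; adjusted p = 0.708 with an estimated correlation). The smooth muscle, PI3K and TGF-beta scores are those that followed the Gapdh ratio within groups (r = -0.86, -0.79 and -0.90). The lists of kidney, FOXO targets, adipose tissue, cell death, endothelium, erythroid cells, oviduct and surface epithelium passed at no step, the smallest adjusted p being 0.0695. For the PD14 step 2415 probe sets had an unadjusted p under 0.05 and 1821 genes (12.5%, chance 10%) had groups that did not overlap. Leaving out 1 array moved the count of 62 to 13, 31 and 10 without PD7 replicates 1, 2 and 3 and to 9, 3 and 376 without PD14 replicates 1, 2 and 3, and the fit without the 7 arrays gave 1046. Without PD7 replicate 3 the camera adjusted p was 0.144 for maternal-effect, 0.0727 for smooth muscle, 0.0849 for PI3K and 0.158 for TGF-beta genes, without PD14 replicate 2 it was 0.079 for macrophages, and without PD14 replicate 3 it was 0.553 for cell division and 0.211 for ribosomal proteins.

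**Figure D4:**
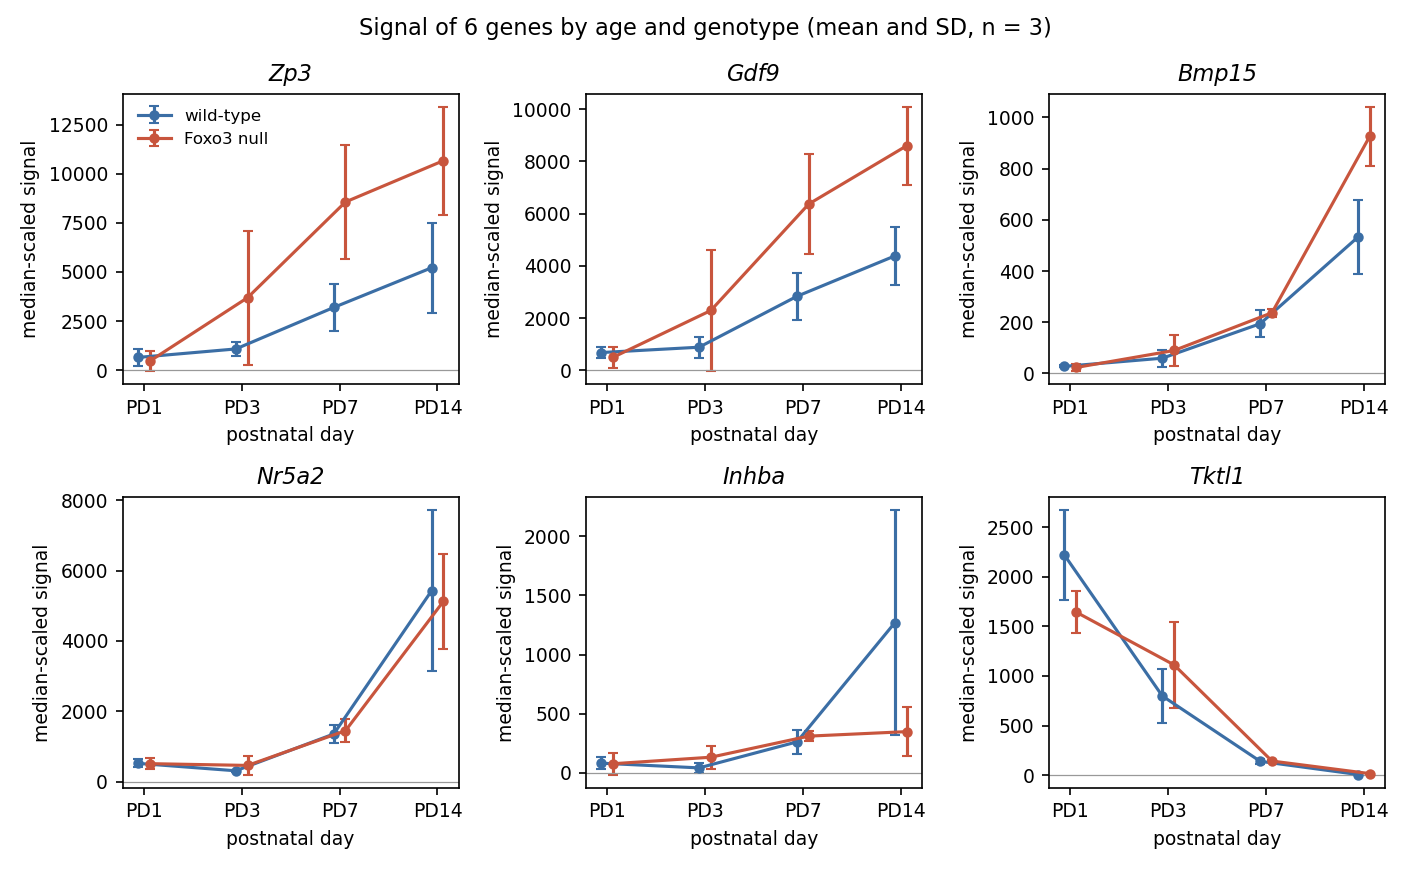
Median-scaled signal (linear axis) of Zp3, Gdf9, Bmp15, Nr5a2, Inhba and Tktl1 in wild-type and Foxo3 null ovaries against postnatal day. Points are means and bars SD of 3 arrays. Nr5a2 in wild-type ovaries goes from 306 on day 3 to 5428 on day 14, and Tktl1 from 798 to 5.91.

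The microdissected cells asked which genes of the young ovary belong to the oocyte. On the array of primary oocytes 1157 of 18193 genes were at least 4-fold above the array of surrounding somatic cells and 150 were at least 4-fold below (557 below with signals as deposited and 367 with quantile normalization). All folds between single arrays include the pseudocount of 23.4. Where the dimmer array read below it, as for Rfpl4, Cpa1 and Cnn1 here, the fold is set largely by the pseudocount and is only approximate. Rfpl4, an egg-specific gene, read 2350 against 5.5 (82.2-fold), Cpa1 was 61.8-fold and the apoptosis regulator Bcl2l10 24.2-fold higher. Zp3 was 16.7-fold, Nobox, an oocyte homeobox factor, 12.4-fold, Gdf9 12.2-fold and Kit 8.90-fold higher, and Foxo3 itself was 6.00-fold higher (6330 against 1040). The median log2 ratio was 3.29 for zona genes (9 of 9 higher), 3.02 for maternal-effect genes (20 of 21) and 2.64 for germ cell regulators (18 of 19). It was -0.40 for granulosa genes, -0.85 for stroma and -1.89 for smooth muscle genes (10 of 11 lower), with the contractile proteins Cnn1 15.3-fold and Tagln 10.8-fold lower. The all-gene median was 0.22, and both arrays had strongly shortened RNA, with Gapdh ratios of 20.7 and 27.0. The somatic array itself read 2060 for Zp3 and 1980 for Gdf9, and the oocyte array read 6570 for the collagen gene Col1a2. Whether either sample held RNA of the other cells was not tested, so these folds need not be those of pure cells. None of the single-array comparisons has replicates, so their folds carry no error.

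Unfertilized eggs were set against the cumulus granulosa cells removed from them. In eggs 953 genes were at least 4-fold higher and 11 at least 4-fold lower. Gdf9 was 87.8-fold and Zp3 40.9-fold higher. Rfpl4 read 10300, Pkd2l2 11000, Nlrp4f 9240 and Bmp15 4850 in eggs, and all 4 lay below the pseudocount in cumulus cells, so no fold is given for them. The median log2 ratio was 6.74 for maternal-effect genes (21 of 21 higher), 5.35 for zona genes and 1.93 for germ cell regulators. Members such as Rfpl4 and Bmp15 lay below the pseudocount in cumulus cells, so the size of these medians depends on it in part. Genes of cumulus expansion and luteinization had a median of -0.21, and Inhba read 5540 in eggs and 4310 in cumulus cells. The gene with the largest ratio in favour of cumulus cells was Gria2, 6.48-fold.

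Eggs were further compared with microdissected oocytes, as a later stage of the same cell type. Eggs were at least 4-fold higher for 1702 genes and lower for 264, around an all-gene median of 0.32. This balance depended on the scaling, with 518 higher and 766 lower for signals as deposited and 631 and 531 with quantile normalization. The Gapdh ratio was 2.94 for eggs and 20.7 for microdissected oocytes, and cumulus cell transcripts were abundant on the egg array, so the differences below are not those of the cell stage alone. Some oocyte genes were lower in eggs: Zp2 44.3-fold, Nobox 26.6-fold, Zp3 13.9-fold and Figla 12.6-fold, with medians of -1.28 for zona genes and -1.41 for germ cell regulators. Bmp15 was 4.17-fold higher. Maternal-effect genes had a median of 0.30 (13 of 21 higher), near that of all genes and above only 1.3% of random lists of similar brightness, and the oocyte-enriched set, chosen in part on the egg array, had 0.99 (301 of 399 higher, above 22.1%). For the maternal-effect list the direction depended on the scaling, with -0.57 for signals as deposited and -0.30 with quantile normalization. The collagen gene Col1a2 was 38.2-fold lower (149 against 6570), and whether the microdissected oocytes carried RNA of other cells was not tested. Genes of luteinizing follicle cells were higher in eggs, among them Cyp11a1, the enzyme that opens steroid synthesis (6330 against 16.6, below the pseudocount), Inhba (100-fold) and Tnfaip6, of the expanding cumulus matrix (66.3-fold). The median was 2.83 for cumulus expansion genes (11 of 12 higher), 2.49 for cholesterol synthesis and 2.51 for early stress.

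Ovary-selective genes were sought by comparing ovaries with 13 somatic tissues. In adult ovary 45 genes were at least 4-fold above the highest somatic tissue, and 20 of them belonged to the oocyte-enriched set. The largest were Cst12 (42.5-fold), Serpina5 (36.1-fold), the prostaglandin receptor Ptgfr (17.1-fold, 6130 against 336 in kidney), the estradiol-forming enzyme Hsd17b1 (13.7-fold), Elobl (13.1-fold) and the AMH receptor Amhr2 (13.1-fold). Outside the 15 largest, Foxl2 was 4.74-fold, Gdf9 4.48-fold and Bmp15 4.42-fold higher, chosen after their values were seen. The postnatal wild-type ovaries gave 84, 52, 100 and 114 such genes at PD1, PD3, PD7 and PD14, of which 29, 26, 60 and 80 were oocyte-enriched. Their RNA was amplified and that of the adult tissues was not, so only adult ovary is compared like for like. At PD3, wild-type replicates 2 and 3 also had high Gapdh ratios (8.64 and 11.7). Gtsf1 (65.4-fold), Dppa3 (63.5-fold) and Figla (53.1-fold) were among the largest at PD1, and Nlrp14 (79.4-fold), Elobl (63.4-fold) and Zp3 (43.2-fold) at PD14. Marker genes fixed for the somatic tissues read highest on the array of that tissue, for example a mean log2 signal of 13.8 for liver genes in liver against 10.1 in placenta, the next highest. The 3 measured Y-linked genes went against a label. They read highest on the Kitl mutant testis (8.51) and next on the adrenal gland (8.47), an array labelled female, so its sex label is in doubt.

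The Kitl mutant testis, compared with adult wild-type testis, asked which transcripts belong to male germ cells. At least 4-fold lower were 1758 genes, among them the spermatid proteins Tnp1 (1.95 against 11500) and Tnp2 (3.12 against 10100), the testis lactate dehydrogenase Ldhc (8.8 against 13400) and Fabp9 (5.66 against 9320). All 4 lay below the pseudocount in the mutant, so no fold is given. Spermatocyte and spermatid genes were lower in 24 of 24 (median -6.99), and meiotic prophase genes in 23 of 23 (-3.48). Where members read below the pseudocount in the mutant, the size of these medians depends on it. At least 4-fold higher were 1216 genes, led by angiotensinogen (Agt, 88.4-fold). Sertoli cell genes were higher in 14 of 14 (median 1.14), Leydig cell genes in 7 of 7 (1.69), macrophage genes in 12 of 13 (1.70) and spermatogonial genes in 7 of 12 (0.35). Kit was 5.73-fold and Kitl 8.08-fold higher, and Ddx4 was 14.9-fold lower. The arrays differed in age, 16 weeks against 6 weeks. The wild-type testis is titled FVB and the title of the mutant array names no strain, so a difference in strain is possible as well.

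**Figure D5:**
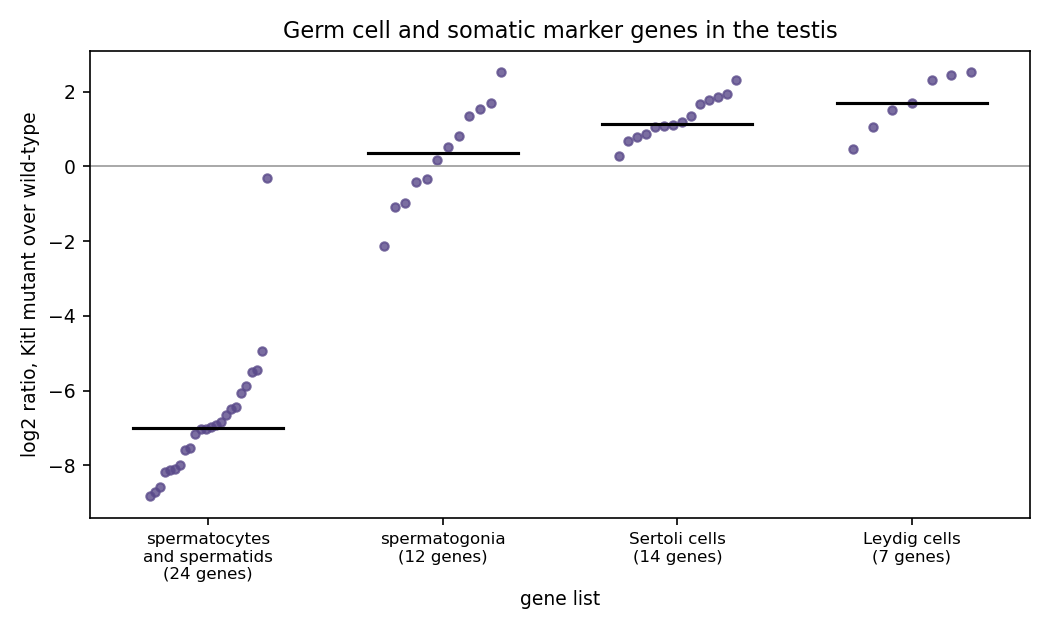
Log2 ratio of Kitl mutant over wild-type testis (1 array each) for marker genes of spermatocytes and spermatids (24 genes), spermatogonia (12), Sertoli cells (14) and Leydig cells (7); points are genes and lines are medians. The medians are -6.99, 0.35, 1.14 and 1.69, all with the pseudocount added.

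The Foxo3 null and wild-type embryos differed little, with a correlation of 0.978 across genes, which are not independent replicates. The probe set shared by Foxo3 and Gm38485 read 71.0 in the null and 82.9 in the wild-type embryo, so it did not check their genotype labels. By fold 1 gene was at least 4-fold higher and 0 were lower. Tmem38b was 3.02-fold higher, and Uroc1 was 3.44-fold and Rps27 3.35-fold lower, with 1 array per genotype. Ribosomal protein genes were lower in 15 of 15 (median -0.33) and mitochondrial respiration genes in 20 of 22 (-0.20).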

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

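The split counts and the limma test of the difference between ages were planned, the camera tests of lists for that difference were added later, and the tests of RNA quality, oocyte growth, oocyte share, a wrong label, cumulus RNA and scaling were chosen after the result they bear on was seen.

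Several gene lists differed in their genotype effect between successive ages, by a camera test of the difference itself. From PD1 to PD3 the effect rose for maternal-effect genes (by 1.39 log2 units, adjusted p = 0.00819), germ cell regulators (0.89, adjusted p = 0.0106), cell division (0.91, adjusted p = 0.00819), cholesterol synthesis (0.85, adjusted p = 0.0482) and mitochondrial respiration (0.90, adjusted p = 0.0482). In the same step it fell relative to other genes for kidney and mesonephric genes (-0.40, adjusted p = 0.0281) and ribosomal proteins (-0.10, adjusted p = 0.0482). From PD3 to PD7 it rose for ribosomal proteins (0.41, adjusted p = 0.00861). From PD7 to PD14 it fell for ribosomal proteins (-0.57, 0 of 15 genes higher, adjusted p = 0.000105), surface epithelium (-0.38, adjusted p = 0.0407) and mitochondrial respiration (-0.26, adjusted p = 0.039). None of these held with an estimated correlation, where the adjusted p was 0.371 for the kidney list, 0.862 for the others of the PD1 to PD3 step, 0.995 for PD3 to PD7 and 0.986 for PD7 to PD14. The log2 Gapdh ratio in null less wild-type ovaries also turned from PD1 to PD3, from 0.96 to -0.55, and RNA quality was not tested for these differences. The limma test of the difference between ages called 0 probe sets (965 with an unadjusted p under 0.05).

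The 6 arrays of a comparison can be split 10 ways, too few for a share under 0.05. For the genotype the real counts of probe sets were 0 at each age, so all 10 splits gave as many by construction, and the highest of the other splits was 2 at PD1, 5049 at PD3, 0 at PD7 and 0 at PD14. Counts of gene lists were 0 at PD1 (10 splits as large, highest other 8), 7 at PD3 (1 split, highest other 6), 8 at PD7 (1 split, highest other 4) and 7 at PD14 (1 split, highest other 3). The mean change of the oocyte-enriched genes was 0.388 in size at PD1 (4 splits as large, highest other 0.58), 0.533 at PD3 (3 splits, highest other 0.824), 0.49 at PD7 (1 split, highest other 0.419) and 0.659 at PD14 (1 split, highest other 0.62). These mean changes were not corrected for the shift of all genes, so shifts of whole arrays count in them as well. For the wild-type age steps the counts of probe sets were 2 at PD3 against PD1 (1 split as large, highest other 1), 38 at PD7 against PD3 (2 splits, highest other 4515) and 62 at PD14 against PD7 (1 split, highest other 0), and the counts of lists were 4 (3 splits, highest other 5), 7 (1 split, highest other 5) and 10 (1 split, highest other 5). The splits with 5049 and 4515 probe sets point to a structure of the samples, and both follow RNA quality, with 0 arrays of high Gapdh ratio on one side and 3 on the other. For the mean over ages (highest other 1807) and the difference between ages (highest other 8593) the real count was 0, so all 100 splits drawn within ages gave as many by construction, which says nothing about the genotype.

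The oocyte-enriched genes were higher in null ovaries at PD7 and PD14, with a mean score difference of 0.4 (SE 0.126). Without the 7 arrays of high Gapdh ratio the difference was 0.314 (SE 0.109), which argues against RNA quality as the whole cause. This fit was required only after a first version of the test, and at these ages it drops only wild-type replicate 3. The Gapdh ratio as a covariate left 0.397 (SE 0.131) but could decide little. Within groups the score followed the ratio with r = -0.08, and with r = -0.59 without the 2 most distant arrays. At PD3 the difference was 0.305 (SE 0.179), against 0.294 (SE 0.187) with the covariate and 0.267 (SE 0.206) without the 7 arrays. These values leave RNA quality open, the last resting on 1 wild-type array. A larger share of oocyte RNA would raise the oocyte lists alike. Zona genes (0.724), maternal-effect genes (0.641) and germ cell regulators (0.321) lay within -2.55 standard errors of their common mean of 0.562. These standard errors were taken over the genes of each list and not over arrays. Genes of a list are not independent replicates, so this test cannot decide, and a larger share stays open. Meiotic prophase (-0.0216) was part of this test at first and was taken out after its value was seen. It lay -4.87 standard errors, also over genes, from the mean of 4 lists, which by the rule of this test would count against that explanation. Earlier oocyte growth in null ovaries would make the genotype change follow the wild-type change with age across genes, and the correlation was 0.238 for the change at PD7 with the step from PD3 to PD14 (highest other split 0.238) and 0.01 for the change at PD14 with the step from PD3 to PD7 (highest other split 0.0644), so it cannot be told apart from the noise shared by these arrays. An effect of Foxo3 loss on the number or the growth of oocytes thus stays a hypothesis, for which no oocyte counts were at hand.

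The probe set shared by Foxo3 and Gm38485 read 501 on the array labelled PD3 Foxo3 null replicate 3, a wild-type level, and 61.6 and 90.2 on the other PD3 null arrays. RNA quality of that array is argued against, since its factor over the arrays of low Gapdh ratio in its group was 6.72, while on the other 6 arrays of high ratio the highest factor was 1.79. A wrong label may account for it, as its genotype score over 50 other probe sets stood at 0.0568 on a scale from 0 at the wild-type mean to 1 at the mean of the other null arrays. That score did not separate the remaining arrays, since PD3 null replicate 2 (2.02) lay below PD3 wild-type replicate 2 (2.12), so a wrong label cannot be told apart from the spread between arrays. No biological explanation was tested.

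Transcripts of cumulus cells were abundant on the array of unfertilized eggs, among them Inhba (5540 in eggs, 4310 in cumulus cells). The 415 genes at least 8-fold higher in cumulus cells than in microdissected oocytes had a median log2 ratio of eggs over cumulus cells of -0.332 (interquartile range 0.643), and the fixed list of cumulus expansion genes had a median of -0.21. Scaling, which moves all genes of an array alike, is argued against, since the median of that fixed list in eggs over microdissected oocytes exceeded that of all genes by at least 2.28 log2 units under 3 scalings and ranked above 100% of random lists after rounding; an earlier test with the signals as deposited (-0.726) could not have come out otherwise and was dropped. Cumulus cell RNA in the egg sample is a candidate explanation, as the values it needs are there, although the labels describe a hyaluronidase digestion and washing meant to remove these cells. Transcription of these genes by the eggs themselves was not tested and stays open.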

How the results depend on the processing

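The fits without the 7 arrays of high Gapdh ratio, with the Gapdh covariate, with array weights, with both deposited signals and without the 7 arrays, and the deposited scaling of the lists were chosen after seeing the data, and the other settings were planned. The counts of probe sets in the genotype comparisons stayed at 0 with the trend left out of the model, with the stricter filter and with no filter, and at the 4 single ages also with only the 6 arrays compared, and the named ratios of the single arrays changed sign in 0 of 400 checks. Where a value below moved, the cause was not tested. Signal over background limits weak probe sets, which depend on the pseudocount and the filter. With 3 arrays per group a 2-fold change at PD14 was recovered in 6% of the changed probe sets of the self-test with independent spread and in 0% with the shuffled residuals of the real arrays.

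With signals as deposited the PD7 against PD3 step gave 120 probe sets (110 up, 10 down) and PD14 against PD7 gave 108 (71 up, 37 down); microdissected oocytes were lower in 557 genes, eggs were higher in 518 and lower in 766 against microdissected oocytes, and the null embryo was higher in 3. With quantile normalization 1 probe set passed at PD14 and 1 for the mean over ages (both lower in null), 186 passed at PD7 against PD3 and 97 at PD14 against PD7; oocytes were lower in 367 genes, eggs were lower in 5 against cumulus cells, higher in 631 and lower in 531 against oocytes, and the null embryo was higher in 3.

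With no pseudocount 1 probe set passed at PD14, 0 at PD3 against PD1, 17 at PD7 against PD3 and 13 at PD14 against PD7, and the null embryo was lower in 1 gene. With a pseudocount of the whole common median 9 passed at PD14, 1 for the mean over ages, and 6, 11 and 136 for the age steps; oocytes were higher in 621 genes and lower in 20, eggs were lower in 0 against cumulus cells and in 109 against oocytes, the Kitl mutant testis was higher in 648, the null embryo was higher in 0, and 24 genes were ovary-selective. At 8-fold in place of 4-fold 16 genes were ovary-selective. With no filter PD7 against PD3 gave 8 probe sets; without probe sets whose names end in _x_at or _s_at, PD3 against PD1 gave 4 and PD14 against PD7 gave 38. With only the 6 arrays compared the age steps gave 0, 0 and 0, where fewer arrays set the spread.

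A replicate block by array number gave 1 probe set for the mean over ages, 4 at PD3 against PD1 and 114 at PD7 against PD3. Whether the numbers pair the arrays cannot be told. Among 12 pairs of the same number the correlation of the residuals ran from -0.237 to 0.553. Of these, 8 were above 0.1 and 6 were the best match of their array. Replicate 3 matched its own number best at PD3 (0.549), PD7 (0.206) and PD14 (0.473) but not at PD1 (-0.115). Several arrays of high Gapdh ratio are replicates 3, so number and RNA quality are not separated.

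With an estimated correlation camera called 1 gene list for genotype and 1 for age (22 and 21 with the preset one), and the oocyte-enriched genes had adjusted p = 0.463, 0.336, 0.336 and 0.336 at PD1, PD3, PD7 and PD14. With the rotation test fry of limma 0 and 3 lists passed and the oocyte-enriched genes had adjusted p = 0.232, 0.182, 0.187 and 0.15. Of the 43 list calls, the Gapdh covariate ended 1, the deposited signals 3, the block 4, the mean over all probe sets of the gene 5, the fit without the 7 arrays 10 (1 of them turned in direction) and quantile normalization 12.

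Leaving out the 7 arrays of high Gapdh ratio leaves 1 null array at PD1 and 1 wild-type array at PD3, so all values with these groups, list counts included, rest in part on a single array. In this fit 2 probe sets passed at PD14, 2 for the mean over ages, 0 at PD3 against PD1, 0 at PD7 against PD3 and 1046 (908 up, 138 down) at PD14 against PD7; 35 gene lists passed for genotype, and mitochondrial respiration at PD3 turned direction (camera adjusted p = 0.853). With signals as deposited and without these arrays the values were 7 at PD14, 4 for the mean, 0 at PD3 against PD1 and 800 at PD14 against PD7, with 35 lists, and mitochondrial respiration at PD3 turned direction (camera adjusted p = 0.89). With the Gapdh ratio as a covariate 1 passed for the mean over ages and 6, 66 and 166 for the age steps. Array weights gave 10991 probe sets at PD3, 1381 at PD7, 1470 at PD14, 41 for the mean, 5617 for the difference between ages, and 15338, 19843 and 13289 for the age steps; the weights ran from 0.174 for PD14 wild-type replicate 3 to 8.6 for PD7 wild-type replicate 1.

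Leaving out each array in turn gave 0 to 1 probe sets at PD1 (1 without PD1 wild-type replicate 1), 0 to 2 at PD3 (2 without PD3 wild-type replicate 1), 0 to 1 at PD7 (1 without PD7 Foxo3 null replicate 2), 0 to 3 for the mean over ages (3 without PD3 Foxo3 null replicate 3) and 0 to 1 for the difference between ages (1 without PD3 wild-type replicate 1). For the age steps it gave 0 to 10 (10 without PD3 wild-type replicate 1), 0 to 146 (146 without the same array, 0 without PD7 wild-type replicate 2) and 3 to 376 (376 without PD14 wild-type replicate 3, 3 without PD14 wild-type replicate 2). The oocyte-enriched genes at PD1 had a camera adjusted p from 3.99e-14 to 0.301 (the latter without PD1 Foxo3 null replicate 1), and maternal-effect genes at PD3 from 1.26e-05 to 0.928, turned in direction without PD3 Foxo3 null replicate 1.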

Other observations

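No further test was chosen for this part; the genes named from the fits without the 7 arrays of high Gapdh ratio were chosen after their values were seen.

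The Kitl mutant testis, which lacks most germ cells, also differed from wild-type testis in signalling and metabolic genes. FOXO target genes were higher in 22 of 24 (median log2 ratio 1.58, above 100% of random lists after rounding), PI3K, AKT and mTOR genes in 15 of 17 (1.24), cholesterol synthesis genes in 15 of 16 (1.54) and early stress genes in 14 of 18 (1.49), and Foxo3 itself was 4.43-fold higher. Markers of the remaining somatic cells had medians of 1.14 (Sertoli cells), 1.69 (Leydig cells) and 1.70 (macrophages), so these differences were not separated from the loss of germ cells. Cell division genes were lower in 20 of 24 (-1.40) and genes of ciliated epithelium in 9 of 10 (-4.07). Some ovary-selective genes were shared with the testis: Cst12 read 3650 in adult ovary and 3670 in adult testis, Serpina5 1750 and 1960, and Amhr2 2480 and 3910, whereas Ptgfr read 6130 and 69.6. In eggs cell division genes stood above cumulus cells (median 1.11, 19 of 24 higher). Microdissected oocytes carried more cell division signal than the somatic cells (median 1.41, 23 of 24 higher), and the list of spermatogonial markers was highest on the array of unfertilized eggs (mean log2 signal 8.71) and next on the Kitl mutant testis (8.50).

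In the fit without the 7 arrays Ctxn3, a small cortical membrane protein, was lower in null ovaries at PD14 (-2.12, SE 0.267, limma adjusted p = 0.0194) and Vil1, the microvillus protein villin, was higher (1.73, SE 0.248, limma adjusted p = 0.0479). With all 24 arrays the changes were -2.08 (limma adjusted p = 0.176) and 2.02 (limma adjusted p = 0.366). The PD14 null mean of Ctxn3 was 6.42, below the pseudocount of 23.4, so the size of its change depends on it. With the deposited signals and without these arrays 7 probe sets passed at PD14, among them Sycp3 (-1.40), which stood at -1.16 (SE 0.368) with all arrays.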
